A study of Mus musculus with 1019 samples.

How the data were processed

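The data were inDrops libraries of sorted Tregs from 1 spleen library and 2 libraries of epididymal VAT of male B6 mice aged 20 months. Per the labels' protocols, spleens were dissociated mechanically, VAT was digested with collagenase and dispase, and live cells were sorted on the T cell receptor beta chain, CD4 and CD25. mRNA was captured by oligo dT inside droplets, amplified by in vitro transcription and sequenced on a NextSeq500. The submitters' processing notes name TopHat2 and SAMtools and the mouse genome build mm10, with no versions. The gene annotation used for counting, the cell filter and any removal of doublets were not given in the sources used here. The authors deposited a table of UMI counts, with 1 row per gene symbol and 1 column per cell, not normalized. A second deposited table repeated label values per cell and was not used. Per the labels, each cell also has its number of unique reads, which exceeded the cell's sum in the table by 4 to 75 (median 24).

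Each GEO sample is 1 cell. Every column matched 1 sample by title, and groups came from the source name in the labels. Title numbers separate the 2 VAT libraries, numbered 2 and 3. The spleen titles also carry number 2, but no label pairs the spleen library with VAT library 2. The labels do not say whether these come from separate animals, so a library is 1 sample. No paired analysis was possible because the labels name no animal and pair no libraries. The table listed 23725 genes, of which 13281 had a UMI. Cells held 819 to 4244 UMIs in spleen, 887 to 3725 in VAT library 2 and 916 to 4973 in VAT library 3. At these depths a count of 0 allows up to 5.23, 5.39 and 5.47 CPM (counts scaled to a common library total) in the 3 libraries, taking a floor of 3 counts.

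UMIs were summed over the cells of each library and divided by the library total to give CPM. A gene was eligible with 50 or more UMIs over the 3 libraries and passed the size rule when it was at least 2-fold higher, or at least 2-fold lower, in both VAT libraries than in the spleen library. log2 ratios add 0.5 to each count. Ratios are printed without that addition, with exact conditional binomial (Clopper-Pearson) 95% intervals, and where 1 side had no UMI the fold was computed against the floor of 3 counts per library. Folds against the floor are not lower limits: the exact lower limits are smaller. Ratios below 1 are printed as the inverse where a gene is called lower. These intervals cover counting error only and are too narrow: in genes with 20 to 100 UMIs, cells with a UMI held a median of 1.34 to 1.39 UMIs against 1.05 to 1.07 if UMIs fell independently, so UMIs came in clumps. No count model was fitted: the spleen is 1 library, and the spread between the 2 VAT libraries cannot be taken as that between animals, since the labels name none.

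A total of 25 gene lists was fixed before the data were examined: VAT Treg, Treg core, lymphoid homing and resting, activation and checkpoint, S100 with annexin and cytoskeleton, AP-1 and immediate early, heat shock, NF-kB targets, secreted factors, tissue chemokine receptors and integrins, lipid metabolism, interferon response, cell cycle, glycolysis, T cell receptor and CD4, MHC class I, ribosomal proteins, mitochondrial genome, other T helper genes, and markers of B cells, myeloid cells, CD8 and NK cells, adipocytes, stromal and endothelial cells, and erythroid cells. A member entered with 20 or more UMIs. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries and is not a test. Lists share some genes, such as Areg and Il10 between the VAT Treg list and secreted factors. Several genes of the lists, such as Folr4 (an older symbol of Izumo1r), Trac, Trbc1, Ighm and Hba-a1, were not among the rows. Genes were named by a rule fixed at the same time: the 12 highest and 12 lowest eligible genes by the smaller absolute log2 ratio of the 2 VAT libraries, up to 4 members per list in the direction of its median, and 16 genes always named, among them Foxp3, Il2ra, Cd4 and Klf2. Other genes were named after their values were seen, mainly list members that went against their list. Coordinates are 1-based positions on GRCm38 (mm10) from the GENCODE M21 annotation, which held 22822 of the 23725 symbols. Gene symbols with near-identical copies, such as Hba-a2, Hspa1a, Hspa1b, H2-K1 and H2-D1, may share reads.

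Shares of cells with a UMI were computed after thinning each cell to 800 UMIs without replacement, with exact Clopper-Pearson intervals, and no cell had fewer. Scores per cell were sums of a list's UMIs after thinning, compared by Spearman's rho within a library. Clusters were made within each tissue from counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 20 principal components and the Leiden method at resolution 1 with seed 0. No doublet caller was run; leaving out the 5% of cells with the most UMIs in each library was tried in its place.

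The alternatives fixed together with the lists were TMM factors, DESeq2 size factors, ribosomal genes left out, equal weight per cell, thinning to 800 UMIs, leaving out cells with UMIs of other cell types, leaving out the top 5% of cells, keeping only cells with a Foxp3 UMI, minimums of 20 or 100 UMIs, 1.5-fold and 3-fold rules, leaving out either VAT library, thinning to 600 or 1000 UMIs or not at all, and other cluster settings. Added after the data were seen were the AP-1 and NF-kB genes left out, the higher genes left out of the total, and cells with a UMI counted in place of UMIs.

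The size rule was tested on counts simulated from the real gene levels and library totals with 200 genes changed, in 20 draws over on average 4602 eligible genes with clumped UMIs. Among changed genes still eligible, it recovered 33.9% of those changed 2-fold, 86.9% at 3-fold, 97.8% at 4-fold and 99.9% at 8-fold, and it called 1.06% of unchanged genes. Genes lowered 8-fold often dropped under 50 UMIs, so low genes that fall far are missed. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the last 2 for scaling factors only.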

Results

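The transcriptomes of single regulatory T cells (Tregs) from the spleen and from epididymal visceral adipose tissue (VAT) of male B6 mice aged 20 months were measured by inDrops, a droplet method that tags the 3' end of each mRNA with a unique molecular identifier (UMI). Cells were sorted as DAPI- TCRb+ CD4+ CD25+ in both tissues. The series title also names conventional CD4+ T cells without FoxP3, whereas the labels of these cells describe the CD25+ sort alone. The table held 1019 cells, of which 375 came from 1 spleen library, 330 from VAT library 2 and 314 from VAT library 3, the numbers being those in the labels. The libraries held 573622, 556099 and 548770 UMIs, with medians of 1423, 1565 and 1611 UMIs per cell. The labels named no animal, and cells are not replicates, so each library was treated as 1 sample and no test or p-value was computed. The labels of the spleen cells disagreed among themselves: the source was given as spleen, whereas the tissue field named spleen and visceral adipose together, and the replicate number differed between fields. The cells were placed in the spleen group by their source. Differences are given for both VAT libraries side by side, and all intervals are exact 95% intervals that cover counting error only.

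The first comparison asked which genes differed in level between Tregs of VAT and of spleen. VAT alone was digested with enzymes, so no difference between VAT and spleen given here can be assigned to tissue apart from dissociation. VAT Tregs carried far more mRNA of tissue Treg receptors and cytokines (Klrg1, Il1rl1, Ccr2, Areg, Il10), of immediate early genes (Fosb, Fos, Nr4a1) and of the S100 and annexin families (S100a4, S100a6, Anxa1), and far less of lymphoid homing genes (Ccr7, Bcl2). Foxp3 lay on different sides of the spleen value in the 2 VAT libraries. Of 4635 genes with at least 50 UMIs, 478 were at least 2-fold higher and 204 at least 2-fold lower in both VAT libraries than in the spleen library, and 0 genes passed 2-fold in opposite directions. The higher genes held 2.92% of spleen UMIs and 18.8% and 18.2% of VAT UMIs. The VAT libraries were closer to each other than to the spleen: 970 genes (20.9%) were 2-fold apart between VAT library 2 and spleen and 1002 (21.6%) between VAT library 3 and spleen, against 201 (4.34%) between the VAT libraries. Both VAT libraries were set against the same spleen library, which raises the overlap of their lists. Libraries simulated without changed genes gave on average 36.9 higher and 16.0 lower genes in both simulated VAT libraries. These draws held counting noise with clumped UMIs and no other variation between libraries. They cannot show how many genes an unusual spleen library would add to both lists. Lists of the observed lengths drawn independently would share 80.2 and 30.3 genes. Part of the excess may come from the shared spleen library. With ribosomal protein genes left out of the totals the split moved from 478 higher and 204 lower to 389 and 309.

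**Figure D1:**
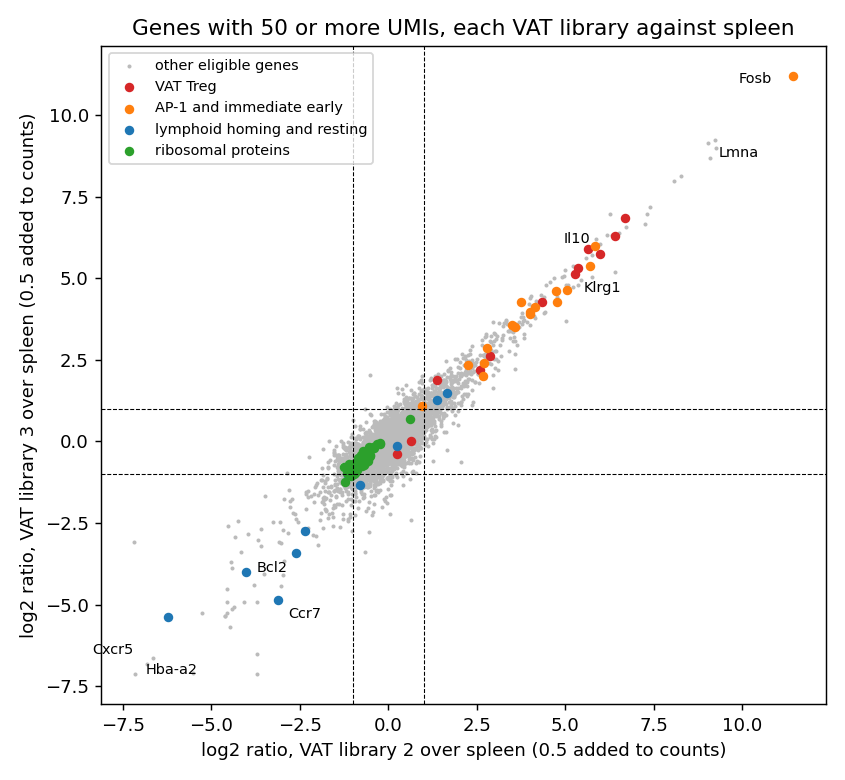
Each point is 1 gene with at least 50 UMIs over the 3 libraries, placed by its log2 ratio to spleen in VAT library 2 (x axis) and VAT library 3 (y axis), with 0.5 added to each count, so that genes with no UMI in a library (Fosb, Hba-a2, Cxcr5) have positions set by that addition. Dashed lines mark 2-fold, colours mark 4 of the gene lists, and 478 genes lie in the upper right corner beyond both lines against 204 in the lower left.

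Genes of the VAT Treg list were higher in VAT as a group. Of 14 measured members (at least 20 UMIs), 11 were at least 2-fold higher in both libraries and 0 were lower, with a median log2 ratio of 3.83 and 3.90, at percentile 100 of expression-matched random lists in both. Klrg1, an inhibitory lectin-like receptor of differentiated T cells, was 38.9-fold higher in VAT library 2 (interval 29.4 to 52.4) and 35.8-fold in VAT library 3 (27.1 to 48.3). Il1rl1, which encodes the IL-33 receptor ST2, was 42.3-fold (25.4 to 76.0) and 41.0-fold (24.6 to 73.7) higher. Gata3, a transcription factor shared with type 2 helper cells, was 6.10-fold (5.06 to 7.39) and 4.58-fold (3.78 to 5.57) higher. Pparg, a nuclear receptor of lipid metabolism, had 2 UMIs in spleen and 49 and 46 in VAT, ratios of 25.3 (6.63 to 215) and 24.0 (6.29 to 204). Batf, Nfil3 and Dgat2 did not reach 2-fold in both libraries, and Cd36, a fatty acid receptor, had 0 UMIs in every library. The floor of 3 counts is 5.23 CPM in spleen and 5.39 and 5.47 CPM in VAT. On mm10, Klrg1 lies on chromosome 6 (122270596 to 122282882) and Il1rl1 on chromosome 1 (40429570 to 40465415).

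Secreted factors and tissue chemokine receptors were also higher in VAT. Among secreted factors, 6 of 10 measured members were higher and 0 lower in both libraries (medians 2.18 and 1.51, percentiles 100 and above 99.9). Areg, a growth factor of tissue repair, was 51.3-fold (33.0 to 84.3) and 61.6-fold (39.7 to 101) higher, and Il10, an anti-inflammatory cytokine, was 67.0-fold (33.8 to 156) and 57.1-fold (28.7 to 133) higher. Cxcl2, a neutrophil chemokine, had 2 UMIs in spleen against 1321 and 985 in VAT, ratios of 681 (188 to 5632) and 515 (142 to 4257). Penk, an enkephalin precursor, was not higher: it had 192 UMIs in spleen and 142 and 59 in VAT, where 1 cell held 82 of the 142. Of 12 measured chemokine receptors and integrins, 8 were higher and 2 lower (medians 1.68 and 1.75, percentile 100 in both). Ccr2, a receptor for monocyte chemoattractants, was 116-fold (45.1 to 429) and 129-fold (49.9998 to 475) higher, and Cxcr6 rested on 2 UMIs in spleen against 205 and 186. Ccr1 had 0 UMIs in spleen and was 45.04-fold and 42.16-fold higher, counted against the floor of 3 UMIs per library. Ccr3 was 12.03-fold and 13.24-fold higher, counted likewise. The 2 lower members were Cxcr3, a receptor of type 1 responses, and the integrin gene Itgae.

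Genes of the Treg core list differed in both directions. Of 14 measured members, 2 were higher and 5 lower in both libraries, and the medians of 0.09 and -0.51 differed in sign (percentiles 59.5 and 2.30). The median of VAT library 3 lay just below the central 95% of random lists, which began at -0.50. The mean of both medians turned from negative to positive under 4 of 15 alternatives, among them cells with a Foxp3 UMI alone. Foxp3, the lineage-defining transcription factor on chromosome X (7573644 to 7595245), was at 1.23 times the spleen level in VAT library 2 (1.02 to 1.47) and at 0.894 times in VAT library 3 (0.732 to 1.09). Il2ra, which encodes the sorted marker CD25, was 2.44-fold (2.10 to 2.83) and 2.23-fold (1.92 to 2.60) higher, and Ctla4, an inhibitory receptor, was 4.83-fold and 4.29-fold higher. Izumo1r, which encodes folate receptor 4, was 17.97-fold (12.9 to 25.7) and 10.6-fold (8.15 to 14.0) lower in VAT. Lrrc32, the surface anchor of latent TGF-beta, had 52 UMIs in spleen and 2 and 1 in VAT, and Nrp1 was 2.16-fold and 2.61-fold lower. Il2rb had 178 UMIs in spleen and 115 and 94 in VAT and did not reach 2-fold. The T cell receptor and CD4 list had medians of -0.48 in both libraries (percentiles 3.12 and 2.92). These lay inside the central 95% of random lists, which began at -0.508 and -0.501. By the rule 1 of 11 members was lower, Cd3d. Cd3e, Cd3g, Cd4 and Lck did not reach 2-fold in both, and Cd4 had 400 UMIs in spleen and 374 and 233 in VAT.

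Genes of lymphoid homing and resting T cells were lower in VAT, with 10 of 14 measured members at least 2-fold lower and 2 higher in both libraries (medians -2.49 and -2.74, percentile 0 in both). Ccr7, which guides T cells to lymph node T zones, was 9.21-fold (4.44 to 22.1) and 36.4-fold (9.72 to 306) lower, and Bcl2, an anti-apoptotic gene, was 17.2-fold (8.50 to 40.6) and 17.0-fold (8.39 to 40.1) lower. Satb1, a chromatin organiser, was 6.35-fold and 11.5-fold lower. Tcf7 had 22 UMIs in spleen and 0 in both VAT libraries, 7.11-fold and 7.02-fold lower against the floor, and Lef1 had 17, 4 and 2. Both genes were below the 50 UMIs needed for the size rule. Klf2 was near the spleen level (97, 111 and 85 UMIs) and S1pr1, the egress receptor, missed 2-fold in 1 library (78, 43 and 29). The 2 higher members were Il7r, 2.63-fold and 2.43-fold, and Ly6c1, 3.21-fold and 2.80-fold.

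Among the 12 highest genes by rank, those in none of the lists were AA467197, Lmna, Ltb4r1, Myadm, Adam8, Lyn and Ier3. Lmna, which encodes nuclear lamin A, had 1 UMI in spleen and 758 and 815 in VAT, ratios of 782 (140 to 30923) and 852 (152 to 33689). Ltb4r1, a leukotriene B4 receptor, and Myadm each had 1 UMI in spleen against 451 and 401, and 247 and 207. AA467197 had none in spleen and was 100-fold and 99.7-fold higher against the floor of 3 UMIs. Against the same floor Adam8 was 26.5-fold and 20.9-fold higher, the kinase gene Lyn 25.4-fold and 16.7-fold, and Ier3 17.5-fold and 15.7-fold. Among the 12 lowest by rank, Cxcr5, the B cell follicle homing receptor, was 16.5-fold and 16.3-fold lower against the floor. The transcriptional regulator Id3 was 18.7-fold and 18.5-fold lower against it. Tbc1d4 had 71, 1 and 0 UMIs, Cd96 59, 1 and 1, Gm8369 and Ift80 each 63, 2 and 1, Gpr18 60, 2 and 1, Hmgn1 60, 2 and 2, and Actn1 80, 3 and 1. Hba-a2 and Ctss, also among these 12, are described with the markers of other cell types.

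AP-1 and immediate early genes, which respond within minutes to receptor signals or stress, were higher in VAT together. Of 18 measured members, 16 were higher and 0 lower in both libraries (medians 3.88 and 3.93, percentile 100 in both). Fosb (chromosome 7, 19302696 to 19310051) had 0 UMIs in spleen and 1336 and 1129 in VAT. Against the floor of 3 UMIs it was 459-fold and 393-fold higher, with exact lower limits of 373 and 319. Fos was 58.9-fold (36.0 to 103) and 66.2-fold (40.6 to 116) higher, Atf3 58.3-fold and 47.0-fold, and Nr4a1, a gene induced by T cell receptor signals, 33.3-fold (26.5 to 42.4) and 25.1-fold (20.0 to 32.1). NF-kB targets were higher for 6 of 12 members and lower for 0 (medians 1.62 and 1.83, percentiles above 99.9). Among the higher were Tnfaip3, 32.7-fold and 27.9-fold, Nfkbiz, 35.4-fold and 29.2-fold, and Nfkbid, 14.6-fold and 13.3-fold, with Icam1 at 4, 70 and 51 UMIs. Heat shock genes did not follow: 0 of 11 members were 2-fold higher or lower in both libraries (medians -0.24 and -0.36, percentiles 20.1 and 9.67). Hspe1 had 284, 144 and 127 UMIs, Hsp90ab1 793, 515 and 591, Hspd1 90, 73 and 56, and Hsph1 88, 30 and 56. Members higher in both libraries by less than 2-fold were Hspa5 (156, 284 and 258 UMIs), Dnaja1 (213, 302 and 235) and Dnajb1 (73, 97 and 82). VAT was digested with collagenase and dispase whereas the spleen was dissociated mechanically. Tissue and dissociation therefore cannot be separated in these values, nor in any other ratio of VAT to spleen.

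The S100, annexin and cytoskeleton list had 11 of 16 members higher and 0 lower in VAT (medians 2.76 and 3.10, percentile 100 in both). The calcium-binding protein genes S100a4, 37.7-fold (30.9 to 46.5) and 41.5-fold (34.0 to 51.2), and S100a6, 32.2-fold (26.4 to 39.6) and 38.1-fold (31.3 to 46.7), were among its most abundant members. Anxa1 was 99.3-fold (38.5 to 366) and 90.2-fold (34.9 to 333) higher. Lgals3, which encodes galectin-3, had no UMI in spleen and was 101-fold and 84.7-fold higher against the floor. In the activation and checkpoint list, 5 of 12 members were higher and 2 lower (medians 0.80 and 0.61, percentiles 99.4 and 98.2). Cd69, a retention and activation marker, was 26.6-fold (18.2 to 40.3) and 23.9-fold (16.4 to 36.2) higher, and Cd44 7.71-fold and 6.72-fold. Gzmb, a cytotoxic protease gene, rested on 1 UMI in spleen against 63 and 44, and Prdm1 was 3.76-fold and 2.69-fold higher. The lower members were Lag3 (18, 1 and 1 UMIs) and Itgae.

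Interferon response genes were lower in VAT by the list median, with 7 of 16 measured members lower and 1 higher in both libraries (medians -0.85 and -1.16, percentiles 0.01 and 0). Ifi47 was 5.96-fold (4.27 to 8.50) and 5.61-fold (4.04 to 7.94) lower, Gbp2 3.48-fold and 3.44-fold, and Iigp1 had 78 UMIs in spleen and 4 and 2 in VAT. The higher member was Ly6a, which encodes Sca-1, at 7.486-fold and 7.002-fold. Of the MHC class I list, 1 of 10 members was lower, the immunoproteasome subunit gene Psmb9 (42, 15 and 18 UMIs), and the medians were -0.30 and -0.27 (percentiles 16.9 and 19.1). Psmb8, Tap2 and Tapbp did not reach 2-fold (log2 ratios of -0.67 and -0.74, -0.38 and -0.70, and -0.31 and -0.38). Ribosomal protein genes were lower by less than 2-fold as a group: the medians over 76 members were -0.78 and -0.63 (percentile 0 in both), 2 members were 2-fold lower in both, and the list held 28.1% of spleen UMIs against 16.5% and 18.3% in VAT. Rps15a was 2.09-fold lower in both VAT libraries, while Rpl28 and Rps18 reached 2-fold in 1 library. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain.

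Metabolic and proliferation lists differed less. In the lipid metabolism list 4 of 17 members were higher and 1 lower (medians 0.72 and 0.61, percentiles 99.7 and 99.4). Dgat1, which catalyses the last step of triglyceride synthesis, was 17.1-fold (9.98 to 31.8) and 15.5-fold (9.01 to 28.8) higher, Plin2, a lipid droplet coat gene, 18.6-fold and 15.2-fold, Fabp5 2.87-fold and 2.24-fold, and Pparg as given for the VAT Treg list. The lower member was Scd2 (51, 6 and 14 UMIs). In the glycolysis list 1 of 13 members, the glucose transporter gene Slc2a3, was higher (3.67-fold and 2.71-fold). Its medians of 0.28 and 0.01 lay inside the random range and their mean turned negative with ribosomal genes left out. Aldoa had 65, 108 and 124 UMIs, Slc2a1 8, 28 and 15, and Tpi1 21, 28 and 26. Of 11 cell cycle genes 1 was higher and 1 lower (medians -0.25 and -0.24, percentiles 21.6 and 24.4), and the mean of both medians turned positive under 2 alternatives. Tubb5 had 318, 232 and 221 UMIs and Cenpa 36, 23 and 29. The list of other T helper genes had 4 measured members (medians -0.13 and -0.36, percentiles 41.4 and 28.7), of which Tnf was higher (7, 59 and 41 UMIs) and Cxcr5 lower, and the mean of both medians turned positive under 1 alternative.

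**Figure D2:**
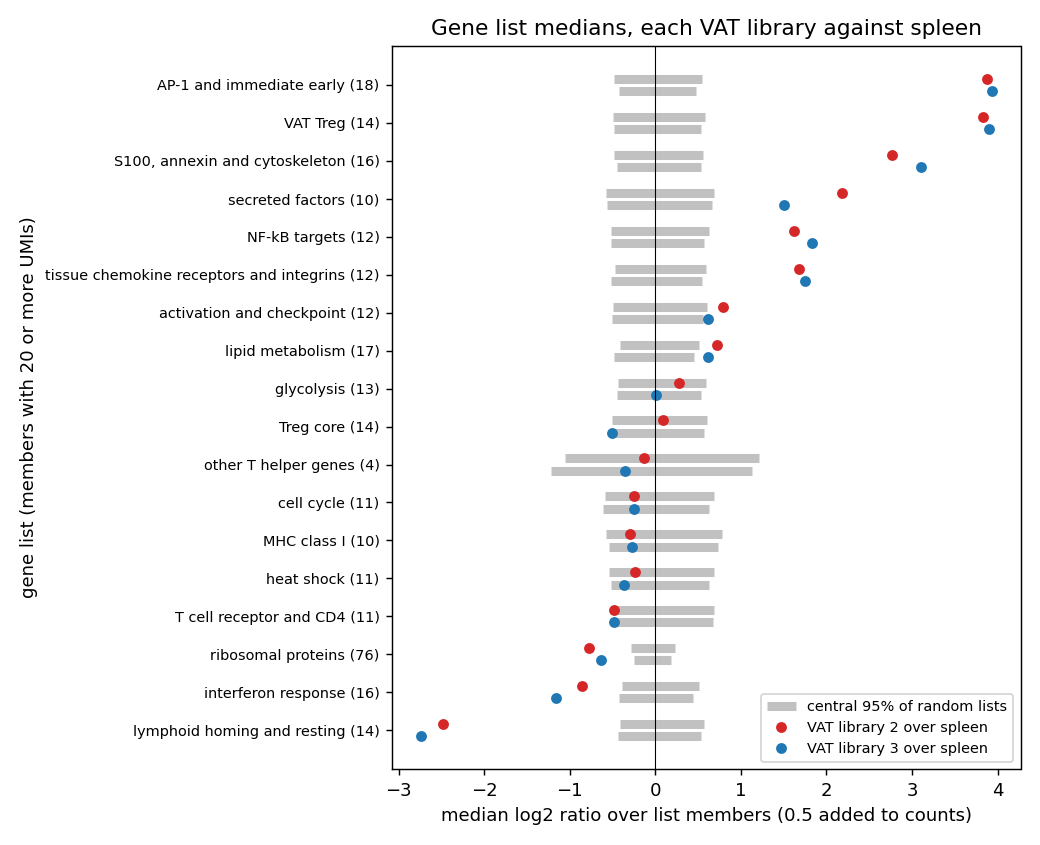
Points give the median log2 ratio to spleen of each gene list (y axis, with the number of measured members) in VAT library 2 (red) and VAT library 3 (blue), and grey bars the central 95% of medians of 10000 expression-matched random lists. The AP-1 and VAT Treg lists lie between 3.83 and 3.93 in both libraries, the heat shock list inside the random range, and the lymphoid homing list at -2.49 and -2.74.

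Shares of cells with a UMI were compared after each cell was thinned to 800 UMIs, so that UMI totals were equal. A Klrg1 UMI was seen in 2.67% of spleen cells (interval 1.29 to 4.85), 73.6% of cells of VAT library 2 (68.5 to 78.3) and 79.3% of VAT library 3 (74.4 to 83.6), and in 3.20%, 83.9% and 89.2% without thinning. Il1rl1 was seen in 0.800%, 47.9% and 47.5% of cells, Gata3 in 12.5%, 54.8% and 51.3%, Areg in 1.07%, 52.7% and 54.5%, and Il10 in 0.533%, 20.3% and 19.7%. Foxp3 was seen in 24.3% (20.0 to 28.9), 26.4% (21.7 to 31.5) and 17.2% (13.2 to 21.8), and in 34.7%, 38.8% and 31.2% unthinned. Izumo1r was seen in 52.5% of spleen cells against 3.33% and 6.69%. At least 1 UMI of the VAT Treg list was held by 26.1% of spleen cells (21.8 to 30.9) against 97.9% and 96.2% of VAT cells, and at least 1 UMI of the AP-1 list by 63.2% against 99.7% and 100%. No cell was too shallow for thinning.

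Markers of other cell types were counted as a guide to RNA from outside the sorted cells, although the source of their UMIs was not settled. Hba-a2, an alpha globin gene of red cells, had 73 UMIs in 52 spleen cells and 0 in both VAT libraries, at least 23.6-fold and 23.3-fold lower, and was seen in 7.73% of thinned spleen cells (5.24 to 10.9). The erythroid list held 116 UMIs in spleen and 1 and 1 in VAT. Spleen shares below that of Hba-a2, such as those of Klrg1, Il1rl1, Areg and Il10, were therefore not read as expression from the share alone. Ctss, a lysosomal protease gene of antigen-presenting cells, had 206 UMIs in spleen and 8 and 6 in VAT, 25.0-fold (12.4 to 58.6) and 32.8-fold (14.8 to 90.5) lower. In the whole table Cd79a had 0 UMIs, Lyz2 had 0, 1 and 1, and C1qa 0, whereas Cst3, also of the myeloid list, had 46, 112 and 118 and was 2-fold higher in both VAT libraries. The B cell list held 93, 17 and 37 UMIs, of which Cd74 had 60, 8 and 14 and H2-Eb1 6, 6 and 22, the myeloid list 266, 132 and 140, mostly Ctss and Cst3, the CD8 and NK list 89, 44 and 53, the adipocyte list 5, 7 and 6, and the stromal and endothelial list 35, 16 and 18. No gene of the mitochondrial genome was among the rows.

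**Figure D3:**
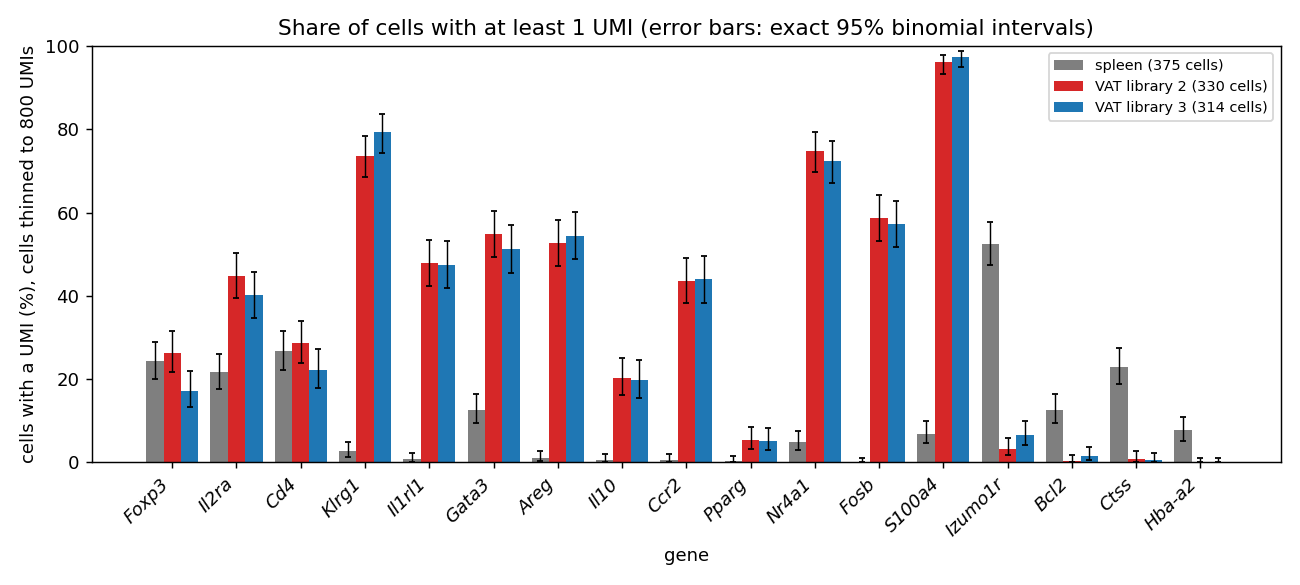
Bars show the share of cells with at least 1 UMI of each gene after thinning to 800 UMIs per cell, in the spleen (grey, 375 cells), VAT library 2 (red, 330 cells) and VAT library 3 (blue, 314 cells), and error bars are exact 95% binomial intervals. Klrg1 was seen in 2.67%, 73.6% and 79.3% of cells, Izumo1r in 52.5%, 3.33% and 6.69%, and Foxp3 in 24.3%, 26.4% and 17.2%.

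Within a library, the scores of different lists were weakly correlated across cells. Across VAT cells, Spearman's rho of the AP-1 list with the VAT Treg list was 0.080 and 0.095 in VAT libraries 2 and 3, and of the AP-1 list with the heat shock list 0.082 and -0.071. The lymphoid list with the VAT Treg list gave -0.10 and 0.0039, and with the S100 list 0.079 and 0.028. In the spleen library the same 4 pairs gave 0.13, 0.14, -0.13 and 0.10. At 600 and 1000 UMIs per cell the spleen value of the lymphoid list with the S100 list turned to -0.020 and -0.031, and that of the AP-1 list with the heat shock list was 0.051 and 0.034. In VAT at 600 UMIs, the AP-1 list with the heat shock list turned to -0.013 in VAT library 2, and the lymphoid list with the VAT Treg list to -0.011 in VAT library 3. At 1000 UMIs the lymphoid list with the VAT Treg list turned to 0.0007 in VAT library 2 and -0.020 in VAT library 3. The counts per cell limit these values: rho between alternate genes of 1 list was 0.44 and 0.36 for the AP-1 list in VAT but only 0.090 and 0.14 for the VAT Treg list. For the lymphoid list it was 0.12 and 0.022, and -0.14 and -0.094 at 600 UMIs. Clustering each tissue on its own gave 11 clusters of 21 to 54 cells in spleen and 11 of 27 to 85 cells in VAT, none of which had more than 1 of the fixed cell type markers among its 10 leading genes, and none was named. Each VAT cluster held cells of both libraries. At a resolution of 0.5 the spleen gave 1 cluster and VAT 2, so the division into clusters depended on the setting. Some leading genes recurred with 10 principal components and with 1000 variable genes. A VAT cluster had Irf8, Tnfrsf9, Ier3 and Mt2 among its 10 leading genes (41 cells, then 61 and 70). Its median UMIs per cell were 2048, the highest of the 11 VAT clusters, then 1793 and 1720.5, which were not the highest. No doublet caller was run, so a part of depth or doublets in this cluster is not excluded. A spleen cluster had Gadd45b and Dusp1 (39 cells, then 65 and 57). Whether these clusters held the same cells was not examined.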

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

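None of the 66 named genes that passed the size rule changed sign under any alternative run, while 3 that did not pass it (Foxp3, Klf2 and Hspd1) did. Sizes were less stable: 452 values of named genes under alternatives moved by more than the SD of the VAT libraries, and 886 did not. As means of the VAT libraries, the log2 ratio of S100a6 was 5.12 (3.02 to 5.37 under alternatives), Cd69 4.63 (3.30 to 4.88), Fosb 11.3 (8.77 to 11.6) and Il10 5.87 (4.92 to 8.70). Of 18 list medians, 14 kept their sign, and those of Treg core (4 of 15 alternatives), cell cycle (2 of 15), glycolysis (1 of 15) and other T helper genes (1 of 12) did not. The alternatives with AP-1 and NF-kB genes left out, with higher genes left out of the total, and with cells counted in place of UMIs were chosen after seeing the data. List medians below are means of the 2 VAT libraries and counts are higher, lower and between the VAT libraries, against 478, 204 and 201 as reported. Counts moved with the genes eligible and the fold required: 285, 97 and 105 with cells thinned to 800 UMIs (2606 eligible genes), 252, 79 and 130 in cells with a Foxp3 UMI (1938 eligible), 783, 479 and 847 with a minimum of 20 UMIs, 298, 85 and 31 with 100, 831, 593 and 879 at 1.5-fold, and 264, 82 and 36 at 3-fold. Lower genes numbered 309 with ribosomal genes left out, 130 with the higher genes left out of the total, and 343 to 409 with 1 VAT library left out; genes apart between the VAT libraries numbered 361 with cells counted. The share of higher among passing genes was 70.1% as reported and 55.7% with ribosomal genes left out, which moved the median of all genes to -0.17 and -0.19, and 83.5% with the higher genes left out of the total, which moved it to 0.30 and 0.23. Leaving out AP-1 and NF-kB genes left 489 higher and 176 lower genes. The VAT Treg median of 3.87 was 3.93 with TMM, 3.67 without ribosomal genes, 3.98 with cells weighted alike, 4.51 thinned, 5.09 without cells holding UMIs of other types, 4.02 without the top 5% of cells, 4.46 in Foxp3 cells, 4.76 at 100 UMIs, 3.93 without AP-1 genes, 4.12 with higher genes out of the total and 3.36 with cells counted. The AP-1 median of 3.91 was 3.97 with TMM, 3.95 with DESeq2 factors, 3.71 without ribosomal genes, 3.86 with cells weighted alike, 3.84 thinned, 3.95 without cells of other types, 3.82 in Foxp3 cells, 3.99 at 100 UMIs, 4.16 with higher genes out of the total and 2.93 with cells counted. The lymphoid median of -2.61 was -2.81 without ribosomal genes, -2.21 thinned, -2.22 in Foxp3 cells, -1.90 at 100 UMIs, -2.36 with higher genes out of the total and -2.20 with cells counted. Other list medians that moved by more than 1.5-fold were those of NF-kB targets (1.72 as reported, 2.75 at 100 UMIs), secreted factors (1.85, and 2.65 in Foxp3 cells), activation (0.70, and 1.31 in Foxp3 cells), chemokine receptors (1.72, and 2.35 without cells of other types), S100 genes (2.93, and 2.05 with cells counted) and interferon response (-1.01, and -1.61 at 20 UMIs), each given at its farthest alternative. Apart from these constructions the cause was not tested. The filter on other cell types removed 123 of 375 spleen cells, and its lists hold Ctss, Cd74 and Cst3. Clusters numbered 2 in VAT and 1 in spleen at resolution 0.5, against 11 and 11. Of the correlations between list scores, 7 of 16 values under other thinning depths moved by more than the SD of the VAT libraries. Depth limits both sides, and a gene needs 50 UMIs to be eligible. Several lower genes rest on 0 to 3 UMIs in VAT, and the 12 highest genes by rank on 0 to 4 UMIs in spleen.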

Other observations

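Tests chosen only after their result was seen were those of the heat shock list, of the ribosomal list against all genes, of ribosomal pseudogenes, of globin UMIs per cell, of B cell markers and of myeloid markers without Cst3; the genes in the next 2 paragraphs were also picked after their values were seen.

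Among abundant genes in none of the lists, several regulators and cytoskeletal genes were higher in VAT. Gadd45b, a stress and NF-kB inducible gene, had 43 UMIs in spleen and 1327 and 1412 in VAT, and Rgs2, a regulator of G protein signalling, 44, 1311 and 1404. Cdkn1a, the cell cycle inhibitor p21, had 3, 310 and 283 UMIs, the transcription factor gene Klf4 4, 209 and 211, the cAMP-responsive repressor gene Crem 20, 276 and 276, and Hilpda, a lipid droplet gene induced by hypoxia, 31, 431 and 393. Mmp9, a matrix metalloproteinase gene, had 6, 138 and 173, and the actin-related genes Tagln2 and Actg1 were 7.44-fold and 8.48-fold, and 3.50-fold and 3.16-fold, higher. On the lower side, Ms4a4b was 14.1-fold and 21.7-fold lower in VAT, Evl, an actin regulator, 22.9-fold and 39.5-fold, Smc4 8.63-fold and 8.52-fold, Ltb, which encodes lymphotoxin beta, 3.38-fold and 4.29-fold, Foxo1, a transcription factor that drives homing genes, 2.99-fold and 4.60-fold, and Nt5e, which encodes the ecto-nucleotidase CD73, 7.998-fold and 13.5-fold.

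Between the VAT libraries, 31 of 2634 genes with at least 100 UMIs were 2-fold apart. Among them were Tnfrsf9, with 96 UMIs in VAT library 2 and 30 in VAT library 3, and Penk, with 142 and 59. Penk was held by few cells, 14 and 5 in the 2 libraries, and single cells held 82 and 29 of its UMIs. Given that the tissue field of the spleen cells also names adipose tissue, the VAT Treg list was counted per cell after thinning to 800 UMIs. In the spleen library 1 of 375 cells reached the VAT median of 8 UMIs, against 179 of 330 and 148 of 314 VAT cells. The VAT shares at this cut follow from the choice of the median. At 5 or more UMIs the numbers of cells were 10, 250 and 232, and at 1 or more 98, 323 and 302. A few VAT cells in the spleen library are therefore not excluded.

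The higher level of AP-1 genes in VAT was weighed first. The heat shock list argues against a dissociation stress response in which heat shock genes rise in VAT over spleen as far as AP-1 genes. Its medians were -0.24 and -0.36 with 0 of 11 members 2-fold higher. Hspa5, Dnaja1 and Dnajb1 were higher by less, and a small response is not excluded. A heat shock response in both tissues would not show in these ratios. Hspa1b had 253 UMIs in spleen and 208 and 164 in VAT, and Hspa1a 80, 57 and 71. A minority of strongly affected cells is argued against as well: 95.2% and 94.3% of cells in VAT libraries 2 and 3 held more AP-1 UMIs than the 95th percentile of spleen cells, which was 6 of 800. Enzyme digestion, used for VAT alone, acting on immediate early genes without heat shock genes cannot be told apart from tissue, since 0 libraries separate digestion from tissue. The tissue itself stays open as a biological explanation, untested.

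The lower level of ribosomal protein genes in VAT was weighed next. If genes higher in VAT merely took a share of the VAT totals, all other genes would be lowered alike, yet the ribosomal medians lay 0.82 and 0.61 below the median of all eligible genes (gaps of -0.82 and -0.61), beyond the range of random lists of that size. With the higher genes left out of the totals the ribosomal medians were -0.52 and -0.39 in place of -0.78 and -0.63, so this share may account for part of the difference but not for the whole. Reads assigned to pseudogenes in place of their parent genes would raise the pseudogenes, and the 4 named ribosomal pseudogenes with enough UMIs had medians of -1.13 and -0.997. These 4 carry a parent gene's name, and pseudogenes under other names were not examined, so such reads are not excluded. A difference in cell state between the tissues remains a hypothesis that was not tested, and the cause may still lie in library preparation of single libraries.

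Globin, Ctss and Cd74 UMIs in the spleen library were weighed last. Hba-a2 had 1.40 UMIs per cell with a UMI, 1.04 times the median of genes with like counts and at most 6 in a cell, which does not separate free red cell RNA from RNA held in cells, so both stay open. B cells among the sorted cells are argued against as the source of Ctss and Cd74, since Cd79a, Cd79b and Ms4a1 together had 1 UMI in the spleen library, 0.485% of the Ctss UMIs, in cells gated on the T cell receptor, although H2-Aa (16, 1 and 0 UMIs) and H2-Ab1 (10, 2 and 0), antigen presentation genes of the B cell list, were also higher in spleen and were not accounted for. For myeloid cells the planned value decided nothing. Together 8 genes abundant in myeloid cells reached 23.8% of the Ctss UMIs, between the bounds set beforehand. Of these 49 UMIs 46 were Cst3, which was higher in VAT (112 and 118 UMIs), and the other 7 genes reached 1.46%. This share, taken without Cst3 after the planned value was seen, argues only against myeloid cells that carry those 7 genes. Myeloid cells with Cst3 and few UMIs of the other 7 genes stay open. H2-Aa and H2-Ab1 were not weighed for myeloid cells. Expression of Ctss by spleen Tregs themselves remains a hypothesis that was not tested.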
